A study of Danio rerio with 20 samples.

How the data were processed

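The series holds 20 RNA-seq libraries of zebrafish embryos. Per the labels' protocols, total RNA was extracted with TRIzol, ERCC spike-in RNA was added, rRNA was depleted and stranded paired-end libraries were sequenced on an Illumina NextSeq instrument. Per the submitters' processing notes, the tools were STAR 2.5.3a and RSEM with the GRCz10 genome; their settings are not given in the sources used here. The deposited table has 32660 entries, of which 555 (1.7%) carry no name or values and stayed out of library sizes and tests.

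The deposited values are estimated counts in set rs1b. In rs1a and rs2 the deposited values are a signal, estimated counts multiplied by 1 factor per library (0.75 to 1.274 in rs1a and 0.382 to 2.032 in rs2), whose origin is not given in the sources used here. The factor was found from the spacing of low values, and after it was removed 84.1 to 90.6% of values up to 20 reads were whole within 0.02. Because the unit was mixed, the planned count test was replaced by limma on log2(CPM + 1) with the same design, and edgeR was run on the rounded reads as an added alternative. A change on this scale understates the change of low genes. ERCC values were not used here, so the planned ERCC scaling was not run, and no change can be read as an absolute amount per embryo.

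CPM values were scaled by TMM (edgeR 4.0.16) and genes were kept by filterByExpr with a minimum count of 10. Tests used limma 3.58.1 with a mean-variance trend and Benjamini-Hochberg adjustment at 0.05, in R 4.3.3. Levels in CPM are scaled over the libraries of their own comparison, and those of the targeted genes over all 20. The TUT47MO model had 12 libraries, 6 matched pairs of set and time as a block, and an early and a late morpholino effect, which left 4 residual degrees of freedom; late minus early tested the difference of effects. Early and late pairs share 1 estimate of the spread. The late pairs varied more: the SD of the cleared median was 0.02 over the early and 0.23 over the late pairs. For the stable median it was 0.02 and 0.19. Late SE and p therefore tend to be too small and early ones too large. The control model compared late with early ConMO libraries with set as a block. The rs1a model had time and morpholino as terms, so its effects are averages over 2, 4 and 6 hpf. Pairing comes from the series text, which calls the sets independent. Libraries of a pair deviated together from their group means, with correlations across genes of 0.448 to 0.929 in the 6 pairs. The group means mix hours, so a shared hour alone would give this, and it is no check of the pairing by set. Libraries of the same group differed by far more than sampling noise (chi-square per degree of freedom 130 to 636). These values include mitochondrial rRNA, whose share of reads differed between sets (48.0% in rs1a and 2.88% in rs1b for ConMO at 6 hpf). They are therefore no measure of the spread of the other genes.

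Classes of genes came from ConMO libraries of the sets other than the one measured. Maternal genes had at least 5 CPM in each early library. Cleared genes were maternal with a mean log2 change of −1 or lower, stable genes were maternal and within 0.5 of 0, and zygotic genes were under 1 CPM early with a late mean of at least 5 CPM. Class medians were compared by two-sided exact sign-flip permutation tests over pairs.

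The designs, gene lists, rule for named genes and most alternatives were fixed before the data were examined. The 19 lists were morpholino targets, other terminal nucleotidyltransferases, mRNA decay machinery, maternal-effect and oocyte genes, germ plasm, reported miR-430 targets, early zygotic regulators, mesendoderm, ectoderm and enveloping layer, yolk syncytial layer, p53 targets, interferon-induced, stress and immediate-early, DNA replication and mitosis, RNA modification and binding regulators, later-stage muscle, blood and neural genes, ribosomal proteins, mitochondrially encoded genes and histones. Of 469 symbols 458 were matched; lists overlap. Lists with at least 3 measured genes were tested with camera (preset correlation 0.01), camera with an estimated correlation and fry, adjusted over 18 lists. Fry tests whether a list moves one way and does not compare it with other genes. Named genes were the 10 highest and 10 lowest late log2 changes (5 and 5 in other comparisons) among genes that passed, had a mean of at least 5 CPM, the same sign in every pair and a symbol that is no clone or prediction name; where none passed, the 5 smallest p; and up to 4 members of each list with the smallest late p. Symbols are those of the table, 737 of which stand on more than 1 entry, and 26269 of 32105 gene IDs were in the reference name table. No genome of this build was used here, so no coordinates are given.

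Alternatives were median-of-ratios scaling, the deposited scaling, DESeq2 1.42.0, edgeR, other filters, pseudocounts of 0.1 and 5, no pair block, each set or time left out, the 6 libraries of a phase alone, the 4 hpf pair counted as late, 6 hpf alone and other class limits. The deposited scaling used the same divisor for every library. In rs1b, whose values are plain estimated counts, it therefore leaves differences in read depth uncorrected. Depth of 1.19e+07 to 3.28e+07 estimated reads detected 20298 to 24154 genes per library. The models were tested on simulated data with 100 genes changed 2-fold and 100 changed 4-fold. The late contrast (18071 genes) recovered 73 and 98 with 36 false calls, the early contrast 59 and 93 with 5, the difference 23 and 88 with 10, the control comparison (17020 genes) 63 and 99 with 12, and rs1a TUT47MO (17044 genes) 29 and 91 with 7. The rs1a simulation changed genes alike at 2, 4 and 6 hpf, so its recovery does not hold for an effect at 6 hpf alone. In the late data 64.3% of genes were called, far more than were changed in the simulation. The 36 late false calls exceed the 0.05 share that the adjustment aims at. Each gene had the same simulated spread in both phases, so the simulation does not show what a larger late spread does. Tables and figures were made with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.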

Results

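RNA levels were measured by total RNA sequencing in zebrafish embryos of the AB strain injected at the 1-cell stage with a control morpholino (ConMO) or with morpholinos against the terminal uridylyltransferases TUT4 and TUT7, singly (TUT4MO, TUT7MO) or together (TUT47MO). A morpholino is an antisense oligomer that blocks translation or splicing of its target. These enzymes add uridines to RNA 3′ ends, and the series asks about their part in maternal mRNA degradation across the maternal-to-zygotic transition. The 20 libraries came from 3 experimental sets. Set rs1a held all 4 morpholinos at 2, 4 and 6 hours post fertilization (hpf), with 1 library each. Sets rs1b (3 and 6 hpf) and rs2 (3 and 5 hpf) held ConMO and TUT47MO. The 2 and 3 hpf pairs are called early and the 5 and 6 hpf pairs late, which gave 3 matched TUT47MO and ConMO pairs in each phase. The labels give no number of embryos or clutches, so p-values measure the spread between these libraries. Depth ran from 1.19e+07 to 3.28e+07 estimated reads per library. Mitochondrial rRNA took 44.6 to 51.6% of reads in 6 rs1a libraries, namely all 4 at 6 hpf and TUT7MO and TUT47MO at 4 hpf, 9.88 to 14.4% in the other rs1a libraries and 1.17 to 9.54% in rs1b and rs2.

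Of the targeted mRNAs, that of TUT7 was lower in all 3 late TUT47MO pairs, by log2 changes of −0.09 and −0.29 at 6 hpf and −1.01 at 5 hpf, and that of TUT4 was not lower in any of them. Log2 changes here were scaled over the 12 libraries of the TUT47MO model, but the CPM values over all 20. The 2 scalings differ: in rs1b, 272 and 247 CPM of the TUT7 mRNA are closer together than −0.29 implies. The gene for TUT4, zcchc11, stood at 99.4 CPM in ConMO and 97.7 CPM in TUT47MO at 2 hpf in rs1a, at 115 and 115 CPM at 4 hpf, and at 123 and 149 CPM at 6 hpf. It was at 121 and 116 CPM at 3 hpf and 126 and 152 CPM at 6 hpf in rs1b, and at 140 and 145 CPM at 3 hpf and 148 and 172 CPM at 5 hpf in rs2. TUT4MO libraries held 96.6, 115 and 127 CPM of zcchc11 at 2, 4 and 6 hpf, and TUT7MO libraries 103, 109 and 150 CPM. ZCCHC6, the gene for TUT7, was at 162, 184 and 263 CPM in ConMO, 160, 192 and 261 CPM in TUT7MO, 168, 174 and 258 CPM in TUT4MO, and 163, 189 and 250 CPM in TUT47MO at 2, 4 and 6 hpf of rs1a. In rs1b ZCCHC6 was at 180 and 172 CPM at 3 hpf and 272 and 247 CPM at 6 hpf in ConMO and TUT47MO, and in rs2 at 175 and 191 CPM at 3 hpf and 257 and 135 CPM at 5 hpf. The late log2 change was 0.17 ± 0.09 for zcchc11 (SE, limma adjusted p = 0.145) and −0.46 ± 0.17 for ZCCHC6 (limma adjusted p = 0.0462). Each is a mean over 3 late pairs, but the SE rests on a spread shared by early and late pairs. The ZCCHC6 call was lost without any 1 of the 3 sets, with −0.19 without rs2, −0.64 without rs1a and −0.51 without rs1b. Under the deposited scaling it was lost at −0.03. It was also lost with edgeR (−0.47), with no filter (−0.44), with a pseudocount of 5 (−0.45), without the pair block (−0.46), with the 6 late libraries alone (−0.43) and with the 4 hpf pair counted as late (−0.32). Without rs2 zcchc11 was called (0.19). Adjusted over the list alone, 0 of these 2 genes passed by limma, at unadjusted p of 0.109 and 0.0294. The labels do not say whether the morpholinos block translation or splicing, so mRNA level is no check of the knockdown.

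In control embryos, maternal mRNAs fell and zygotic genes rose between the early and late libraries. The largest rise was that of akap12b, a kinase-anchoring protein gene, from 1.36 ± 0.417 to 5765 ± 1231 CPM (SD, n = 3; log2 change 11.25 ± 0.11, SE). Next came the otolith matrix gene stm (10.77 ± 0.17), the keratins krt18 (10.55 ± 0.23) and krt4 (10.33 ± 0.17) and the apolipoprotein gene apoeb (10.28 ± 0.23). The largest fall was that of btg4, a deadenylation adaptor of oocytes, from 372.5 ± 76.5 to 17.98 ± 13.6 CPM (−4.50 ± 0.38). Next, leaving out provisional symbols, came the lipase gene lipg (−4.44 ± 0.32), the phospholipase D gene pld1a (−4.32 ± 0.17), trim35-29 (−4.31 ± 0.21) and cdca9 (−4.04 ± 0.28). Limma adjusted p for these 10 ran from 3.02e-08 to 4.48e-05; the rule that named them asked for a passing p and the same sign in the 3 sets. Of 17020 genes tested, 6379 rose and 6104 fell. Without TMM scaling, 2592 rose and 2045 fell.

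Lists of maternal and of zygotic genes followed this course. All 36 early zygotic regulators and all 50 histone genes rose, as did 42 of 43 mesendoderm genes, 28 of 32 ectoderm and enveloping layer genes (1 fell), 13 of 14 yolk syncytial layer genes, 82 of 86 cytosolic ribosomal protein genes and 12 of 13 mitochondrially encoded genes, with the same counts adjusted over the list alone. Of 35 maternal-effect and oocyte genes 33 fell and 2 rose, with the same counts adjusted over the list alone. Camera with its preset correlation called each of these lists (adjusted p from 9.11e-17 to 0.00786), and none of these calls held with an estimated correlation (adjusted p = 0.373 to 0.667 with an estimated correlation). Under the deposited scaling 0 ribosomal protein genes, 0 mitochondrial genes and 5 histone genes were called, while their medians stayed above 0 (1.17, 0.35 and 1.45), and 19 maternal-effect and oocyte genes fell and 0 rose. Of 29 stress and immediate-early genes 19 rose and 6 fell (camera adjusted p = 0.0423; adjusted p = 0.448 with an estimated correlation). Camera did not call the other 9 lists tested. Genes of these lists moved both ways: 27 rose and 20 fell in mRNA decay, 19 and 14 in DNA replication and mitosis, 15 and 15 in RNA regulators, 13 and 5 in p53 targets, 6 and 6 in interferon-induced genes, 7 and 3 in miR-430 targets, 3 and 9 in germ plasm, 2 and 5 in nucleotidyltransferases and 3 and 1 in later-stage genes. Counts adjusted over each list alone were the same, except for 4 rising germ plasm genes.

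In late TUT47MO embryos the mRNAs that control embryos clear stayed higher and the genes that control embryos switch on stayed lower. Cleared maternal genes had a median log2(TUT47MO/ConMO) of 1.25 in rs1a at 6 hpf, 1.40 in rs1b at 6 hpf and 0.94 in rs2 at 5 hpf (mean 1.2 ± 0.23, SD, n = 3), and 95.9 to 96.7% of them were higher in TUT47MO. Zygotic genes had medians of −2.27, −2.30 and −1.19 (mean −1.92 ± 0.63, SD, n = 3), with 90.9 to 93.6% lower. Stable maternal genes had medians of 0.05, 0.21 and −0.16. Where a class lies against 0 depends on the scaling: on the deposited scaling the stable medians were 0.11, 0.86 and 0.12, the cleared ones 1.25, 1.92 and 1.26 and the zygotic ones −2.05, −1.62 and −1.06. The classes held 3257 to 3765 cleared, 2644 to 2887 stable and 921 to 1035 zygotic genes, and those of each set were defined from control libraries of the other 2 sets.

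Relative to stable maternal genes, cleared genes were higher by 1.17 ± 0.05 (SD, n = 3 late pairs; 1.2, 1.19 and 1.11) and zygotic genes differed by −1.95 ± 0.81 (−2.32, −2.50 and −1.02). The two-sided exact sign-flip test gave p = 0.25 for each, the smallest that 3 pairs allow. In the 3 early pairs the cleared genes differed from the stable ones by 0.02 ± 0.02 (SD, n = 3) and in the 4 hpf pair of rs1a by 0.09. By 4 hpf the cleared class of rs1a ConMO had a median change of only −0.12 from 2 hpf, which left little room for a difference. On the deposited scaling the cleared minus stable difference was 1.14, 1.06 and 1.14 in the late pairs; in the 3 hpf pair of rs2 it was 0.006, with both classes high in TUT47MO (0.77 and 0.76). From the early to the late library, the cleared class went down by a median of −1.72 ± 0.33 in ConMO and −0.61 ± 0.15 in TUT47MO (SD over the 3 sets), and the zygotic class up by 3.80 ± 0.41 and 1.77 ± 0.25.

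**Figure D1:**
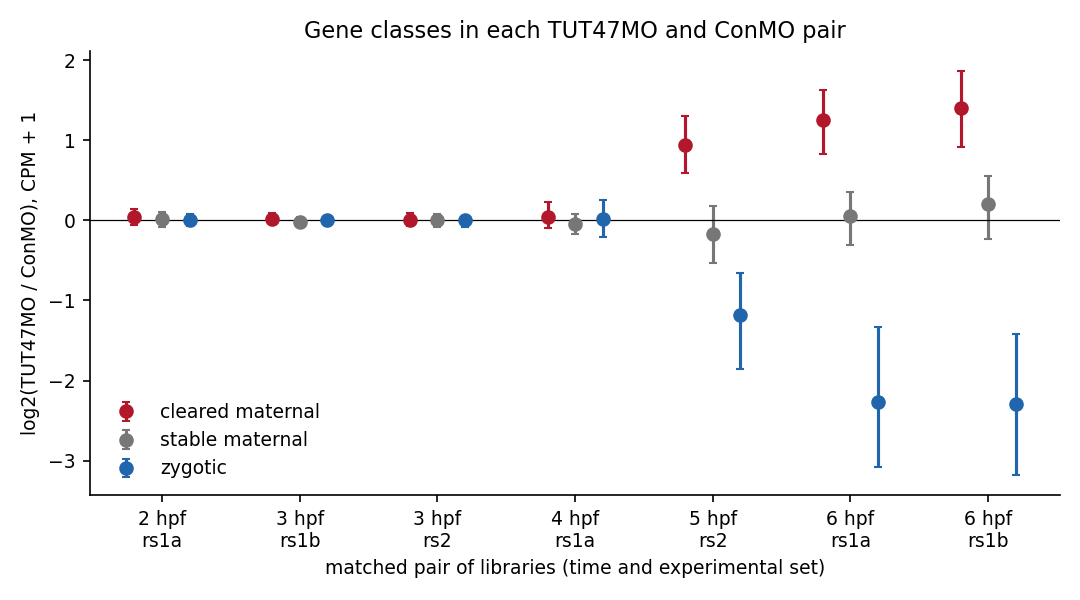
Median log2(TUT47MO/ConMO) on the CPM + 1 scale (vertical axis) for cleared maternal, stable maternal and zygotic genes in each of the 7 matched pairs, ordered by hours post fertilization; bars span the 25th to 75th percentiles of genes. Cleared medians at 5 and 6 hpf lie between 0.94 and 1.40 and zygotic medians between −2.30 and −1.19, while the medians of the 4 earlier pairs lie within 0.05 of 0 after TMM scaling; on the deposited scaling the cleared and stable medians of rs2 at 3 hpf are 0.77 and 0.76. Zygotic genes were chosen as under 1 CPM early, which sets their 2 and 3 hpf medians at 0.

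Gene by gene, the mRNAs with the largest late increase were abundant early and low in late controls. The endothelial lipase gene lipg was at 18.1 ± 11.8 CPM in late ConMO and 130 ± 18.1 CPM in late TUT47MO (SD, n = 3), a log2 change of 2.94 ± 0.23 (SE). It was followed by fam65c (2.91 ± 0.33), the phosphatidate phosphatase gene lipin2 (2.83 ± 0.14), pik3ap1, an adaptor of phosphoinositide signalling (2.75 ± 0.22), and pld1a (2.73 ± 0.12). Lower in the ranking were adob (2.73 ± 0.41), the cryptochrome gene cry1ab (2.69 ± 0.16), the supervillin gene svila (2.67 ± 0.17), rab11fip4b (2.62 ± 0.13) and ildr1b (2.62 ± 0.18). The largest decreases were in genes near 0 early. The actin-bundling gene lcp1 was at 230 ± 50.4 CPM in late ConMO and 8.61 ± 14.7 CPM in late TUT47MO (−6.14 ± 0.71). After it came abcc6b.2 (−4.90 ± 0.69), the adhesion gene alcamb (−4.82 ± 0.54), hkdc1 (−4.82 ± 0.27), and TSTA3 (−4.77 ± 0.57). The others were aldh1a2, which makes retinoic acid (−4.72 ± 0.38), the mesoderm segmentation gene mespab (−4.71 ± 0.50), add3b (−4.62 ± 0.33), mapkapk3 (−4.57 ± 0.22) and anxa1c (−4.54 ± 0.56). Limma adjusted p for these 20 ran from 1.48e-05 to 0.000722; the rule that named them asked for a passing p and the same sign in the 3 late pairs. The symbols adob and TSTA3 each stand on 2 entries of the table, so their reads could be split between copies.

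In all, 5945 genes rose and 5679 fell late among 18071 tested (limma, adjusted p under 0.05), 2436 and 3107 of them by at least 2-fold, and 5795 and 5534 moved the same way in all 3 late pairs. Genes that rose made up 51.1% of calls with TMM and 67.7% with the deposited scaling, under which 3161 fell, but 45.3% with median-of-ratios scaling (5327 rose and 6422 fell), and DESeq2 gave 4988 and 5982. Genes that rose numbered 3904 without rs1a and 3780 without the pair block. With the 6 late libraries alone, whose spread is not pooled with the smaller early one, 4670 rose and 4338 fell.

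Late TUT47MO embryos held more maternal-effect and oocyte mRNA and less mRNA of the embryonic lineages. Of 36 maternal-effect and oocyte genes, 29 rose and 1 fell (29 and 2 adjusted over the list alone). Among them were zar1l (2.58 ± 0.14), the Balbiani body organiser buc (2.44 ± 0.15), the meiotic kinase mos (2.15 ± 0.12) and slbp2, which binds histone mRNA stem-loops (1.95 ± 0.09). Camera called the list higher (adjusted p = 1.7e-07; adjusted p = 0.548 with an estimated correlation). Of 14 germ plasm genes 9 rose and 3 fell, with the same counts adjusted over the list alone. The genes tdrd6 (1.78 ± 0.11), ca15b (1.78 ± 0.10) and rgs14a (1.62 ± 0.13) stood beside buc. Camera gave adjusted p = 0.0202 for germ plasm (adjusted p = 0.739 with an estimated correlation), and with the deposited scaling 9 rose and 0 fell.

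Of 43 mesendoderm genes 36 fell and 0 rose over all genes (36 and 1 adjusted over the list alone). Lower were the segmentation gene her1 (−4.51 ± 0.19), cdx4 (−3.66 ± 0.19), eve1 (−3.45 ± 0.15) and the brachyury gene ta (−2.66 ± 0.12; camera adjusted p = 1.45e-09; adjusted p = 0.438 with an estimated correlation). The call of ta was lost with the 4 hpf pair counted as late (−1.66). Of 33 ectoderm and enveloping layer genes 25 fell and 2 rose, with the same counts adjusted over the list alone. Lower were sox2 (−4.17 ± 0.17), krt17 (−3.51 ± 0.22) and krt4 (−2.77 ± 0.22, a call lost at −1.66 with the 4 hpf pair counted as late), while the maternally supplied sox19b rose (1.35 ± 0.11; camera adjusted p = 4.33e-06; adjusted p = 0.438 with an estimated correlation). Of 14 yolk syncytial layer genes 12 fell and 1 rose, with the same counts adjusted over the list alone. They included slc26a1 (−3.32 ± 0.24), hnf1ba (−3.30 ± 0.19), afp4 (−2.97 ± 0.13; 2 entries share its symbol) and hnf4a (−2.72 ± 0.16; camera adjusted p = 2.87e-05; adjusted p = 0.548 with an estimated correlation). Of 36 early zygotic regulators 18 fell and 5 rose (19 and 6 adjusted over the list alone). The endoderm factor sox32 (−2.40 ± 0.21), apoeb (−2.34 ± 0.15), sox3 (−1.71 ± 0.16) and vent (−1.60 ± 0.15) were among those that fell (camera adjusted p = 0.00767; adjusted p = 0.548 with an estimated correlation). Under the deposited scaling 14 of these regulators fell and 7 rose, and 29 mesendoderm genes fell and 1 rose.

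**Figure D2:**
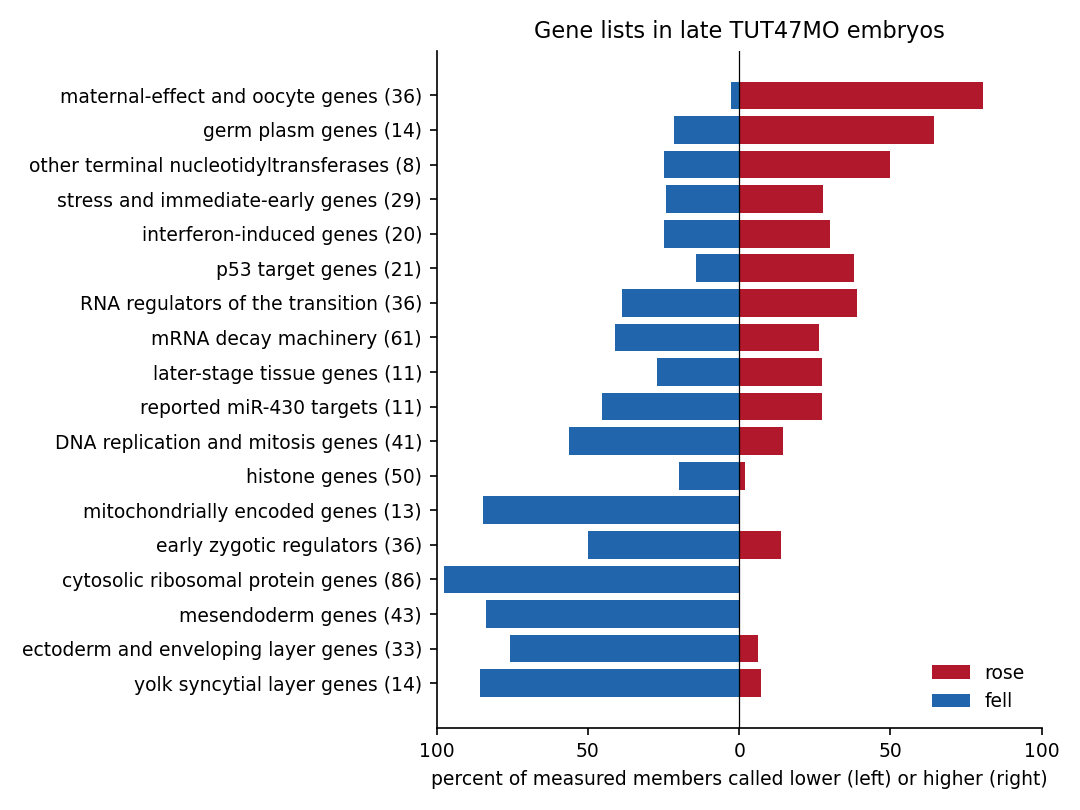
Percent of measured members of each gene list called higher (right of 0) or lower (left of 0) in late TUT47MO against ConMO embryos by limma; the number measured follows each name and lists are ordered by median log2 change. Of 86 ribosomal protein genes 84 were lower and of 36 maternal-effect genes 29 were higher; among the lists shown, under other scalings the medians of the mRNA decay, miR-430 target, later-stage, p53 target and RNA regulator lists change sign, and 0 mitochondrial genes are called with the deposited scaling.

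Ribosomal protein mRNAs fell together, 84 of 86 with 0 rising and the same counts adjusted over the list alone (median −1.25). Examples were rps15a (−1.81 ± 0.13), rpl36a (−1.66 ± 0.11), rpl14 (−1.63 ± 0.14) and rpl4 (−1.28 ± 0.10). Camera called the list (adjusted p = 1.1e-17; adjusted p = 0.548 with an estimated correlation), and 51 were called lower with the deposited scaling. Of 50 histone genes 10 fell and 1 rose (9 and 1 adjusted over the list alone). They included h2afy (−2.42 ± 0.14), h3f3a (−1.88 ± 0.13), h2afvb (−1.34 ± 0.10) and h3f3b.1 (−1.11 ± 0.12), paralogs whose reads may be shared (camera adjusted p = 0.00436; adjusted p = 0.739 with an estimated correlation; fry adjusted p = 0.0664). With the deposited scaling 5 fell and 1 rose, the median went from −0.59 to −0.15 and the call of h3f3b.1 was lost at −0.68. Of 13 mitochondrially encoded genes 11 fell, with the same count adjusted over the list alone. They ran from mt-nd4l (−0.71 ± 0.12) and mt-nd2 (−0.68 ± 0.11) to mt-nd3 (−0.66 ± 0.10) and mt-nd1 (−0.64 ± 0.11; camera adjusted p = 0.00365; adjusted p = 0.739 with an estimated correlation), and 0 were called with the deposited scaling. The call of mt-nd4l was lost with the 4 hpf pair counted as late (−0.42), and those of all 4 without the pair block. Of 41 DNA replication and mitosis genes 23 fell and 6 rose, with the same counts adjusted over the list alone. The helicase subunit mcm6 (−3.57 ± 0.30), the cyclin ccne2 (−2.52 ± 0.13) and cdk1 (−1.22 ± 0.11) fell and gins2 rose (1.43 ± 0.11; camera adjusted p = 0.022; adjusted p = 0.438 with an estimated correlation). With the deposited scaling 7 of these rose and 5 fell.

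Several groups moved both ways. Among 61 mRNA decay genes 25 fell and 16 rose, with the same counts adjusted over the list alone (camera adjusted p = 0.444). The deadenylase subunit gene cnot3a (−1.58 ± 0.09), the decapping genes dcp2 (−1.42 ± 0.11) and edc3 (−1.34 ± 0.11) fell and lsm1 rose (1.49 ± 0.12). With the deposited scaling 6 fell and 16 rose, and the median went from −0.13 to 0.30. Of 8 other terminal nucleotidyltransferases 4 rose and 2 fell, with the same counts adjusted over the list alone (camera adjusted p = 0.289). Of these fam46c (2.15 ± 0.10), PAPD5 (0.93 ± 0.14) and papd7 (0.86 ± 0.12, not called without the pair block) rose and papd4 fell (−0.59 ± 0.10). Under the deposited scaling 4 rose and 0 fell, and with the 4 hpf pair counted as late the calls of PAPD5 (0.59) and papd4 (−0.39) were lost. Of 36 RNA modification and binding regulators 14 rose and 14 fell, with the same counts adjusted over the list alone (camera adjusted p = 0.961). Those that fell included igf2bp1 (−2.53 ± 0.17), ybx1 (−2.36 ± 0.11) and elavl1 (−1.51 ± 0.11). The median of 0.03 became −0.09 with median-of-ratios scaling and 0.43 with the deposited scaling, under which 14 rose and 6 fell. Of 11 reported miR-430 targets 3 rose and 5 fell, with the same counts adjusted over the list alone. The genes cd82b (2.16 ± 0.15), tdrd7a (1.39 ± 0.14) and nanos3 (1.23 ± 0.15) rose and cxcl12a (−0.97 ± 0.20) fell, the last not called without rs1a (−0.81) or without rs1b (−0.80), nor with the deposited scaling (−0.54). Their median was −0.26 and their mean 0.06, while with the deposited scaling the median was 0.07 and 3 rose and 0 fell. Camera gave adjusted p = 0.961 downwards while fry gave adjusted p = 0.0291 upwards.

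Among 21 p53 target genes 8 rose and 3 fell, with the same counts adjusted over the list alone (camera adjusted p = 0.944). Here sesn1 (1.88 ± 0.24), sesn2 (1.56 ± 0.09) and casp8 (0.78 ± 0.15) rose and sesn3 fell (−3.55 ± 0.19). The median of 0.09 became −0.02 with median-of-ratios scaling, under which 8 rose and 7 fell, and 0.38 with the deposited scaling, under which 9 rose and 1 fell. Of 20 interferon-induced genes 6 rose and 5 fell (6 and 4 adjusted over the list alone; camera adjusted p = 0.961). The regulator irf7 rose (1.57 ± 0.36), with the call lost without rs1a (1.34) or rs1b (1.22), and trim25 rose (0.70 ± 0.23), with the call lost without rs1a (0.69), without rs1b (0.41), without the pair block (0.70), with the 6 late libraries alone (0.69) or with the 4 hpf pair counted as late (0.49). The deposited scaling gave 8 rising and 3 falling. Log2 changes of isg20 (−0.31 ± 0.13) and irf1b (−0.22 ± 0.15) did not pass by limma with TMM. With DESeq2 (−0.45) and with median-of-ratios scaling (−0.43) isg20 was called lower. Of 29 stress and immediate-early genes 8 rose and 7 fell (7 and 7 adjusted over the list alone; camera adjusted p = 0.961). The small heat shock gene hspb1 (−3.55 ± 0.29), atf4b (−2.38 ± 0.19) and atf4a (−2.36 ± 0.22) fell and the endoplasmic reticulum chaperone gene hsp90b1 rose (1.26 ± 0.13). The balance of this list rests on TMM: 14 rose and 4 fell with the deposited scaling, and the median went from 0.29 to 0.43. Of 11 measured muscle, blood and neural genes of later stages 3 rose and 3 fell, with the same counts adjusted over the list alone (camera adjusted p = 0.961). Their median of −0.14 became 0.06 with the deposited scaling, under which 5 rose and 3 fell.

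At 2 and 3 hpf no gene passed in TUT47MO embryos. The genes with the smallest unadjusted p were ano10b (0.69 ± 0.17), the ATPase inhibitor gene atpif1a (0.58 ± 0.14), the adaptor complex gene ap3s2 (0.52 ± 0.13), 5.8S rRNA (1.26 ± 0.38, 10 entries share its symbol) and gbgt1l1 (0.45 ± 0.14), all at a limma adjusted p of 1. Limma called 0 of 18071 genes, with 102 at an unadjusted p under 0.05, DESeq2 called 0 (150 unadjusted) and edgeR 0 (199 unadjusted). The 102 are 0.56% of genes, fewer than would pass 0.05 with no effect at all, so the limma test was cautious here. Its spread is shared with the late pairs, and 0 calls do not rule out early changes. With the deposited scaling limma called 3 genes higher, and with the 6 early libraries alone 1, 5.8S rRNA. In each of the 19 lists 0 genes passed by limma, over all genes and adjusted over the list alone. Camera called the early zygotic regulators (median −0.04, adjusted p = 0.00372) and the RNA modification and binding regulators (median −0.05, adjusted p = 0.0138) lower, at adjusted p = 0.985 for both with an estimated correlation.

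The effect of the TUT4 and TUT7 morpholinos differed between phases for 4478 genes with a higher and 4466 with a lower late effect (limma, difference of effects, 18071 tested). Of the latter 1604, and 139 of the former, were under 1 CPM in early ConMO, where the CPM + 1 scale leaves little room for a lower early effect, so for these the test mostly restates the late effect. Among 10668 genes at 5 CPM or more in early ConMO, 3798 had a higher and 2147 a lower late effect. The Hairy-related gene her5 was at 24.7 ± 13.7 CPM in late ConMO and 130 ± 2.82 CPM in late TUT47MO (SD, n = 3), against 1.29 and 0.565 CPM early, a difference of log2 effects of 2.94 ± 0.40 (SE). At 4 hpf of rs1a, which neither phase includes, it was at 85.1 CPM in ConMO and 60.47 CPM in TUT47MO, so the control level was high between the phases in that set. The next were fam65c (2.81 ± 0.47), pik3ap1 (2.80 ± 0.31), lipin2 (2.77 ± 0.20) and lipg (2.77 ± 0.33). On the other side stood genes with at most 1.03 CPM in early ConMO, whose differences mostly restate their late changes: lcp1 (−6.12 ± 1.00), abcc6b.2 (−4.96 ± 0.98), TSTA3 (−4.88 ± 0.80), alcamb (−4.80 ± 0.77) and hkdc1 (−4.76 ± 0.38), and limma adjusted p for these 10 genes ran from 0.000226 to 0.00465. Counts were 2809 and 2519 with the deposited scaling, 1976 and 2573 without the pair block, 1501 and 1495 without rs1a and 2044 and 1814 without rs1b. Without rs1a the calls of fam65c, lcp1, abcc6b.2, TSTA3 and alcamb were lost at 2.71, −5.46, −4.34, −4.36 and −4.13, and without rs1b that of abcc6b.2 at −4.16. The edgeR test did not call lcp1 (−5.24), abcc6b.2 (−8.00, further from 0 than with limma) or alcamb (−4.81).

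Set rs1a compared each morpholino alone with both together. At 6 hpf the cleared class had a median log2 ratio to ConMO of 0.48 in TUT4MO, 1.03 in TUT7MO and 1.25 in TUT47MO, and the zygotic class −0.62, −1.83 and −2.27 (3337 and 999 genes, 1 library each). Measured from its own 2 hpf library, the cleared class had a median change of −1.84 in ConMO, −1.48 in TUT4MO, −0.93 in TUT7MO and −0.73 in TUT47MO, and the zygotic class of 3.85, 3.17, 1.98 and 1.5. The deposited scaling gave −2.45, −2.16, −1.53 and −1.26 for the cleared class, 3.26, 2.56, 1.55 and 1.14 for the zygotic class and −0.70, −0.69, −0.51 and −0.48 for the stable class. Between TUT47MO and TUT7MO at 6 hpf the cleared class differed by 0.23, with 79.3% of genes higher in TUT47MO, and the zygotic class by −0.40, with 18% higher. Between TUT47MO and TUT4MO the medians were 0.76 and −1.55, and between TUT7MO and TUT4MO 0.54 and −1.11. At 4 hpf the cleared class differed from the stable one by 0.06 in TUT4MO, 0.08 in TUT7MO and 0.09 in TUT47MO. The cleared class of ConMO had by then a median change of only −0.12 from 2 hpf. Mitochondrial rRNA took 13.5, 44.7 and 44.6% of reads in the 4 hpf TUT4MO, TUT7MO and TUT47MO libraries and 14.4% in ConMO. With 1 library per morpholino and time these class differences have no replicate check.

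**Figure D3:**
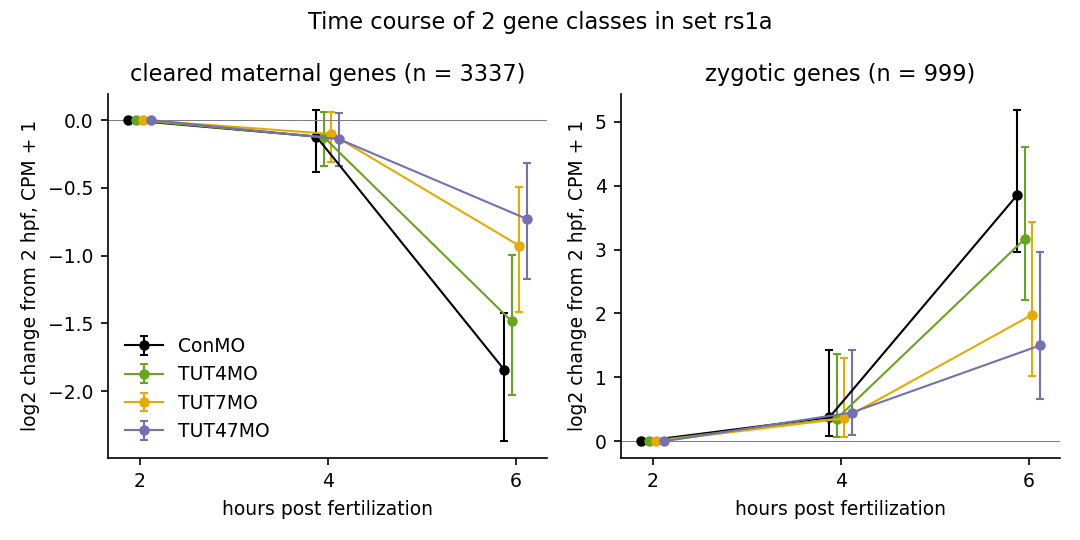
Median log2 change from the same morpholino's 2 hpf library (vertical axis, CPM + 1 scale) of cleared maternal and zygotic genes at 2, 4 and 6 hours post fertilization in set rs1a, 1 library per point; bars span the 25th to 75th percentiles of genes and points are offset sideways. At 6 hpf the cleared medians run from −1.84 in ConMO to −0.73 in TUT47MO and the zygotic medians from 3.85 to 1.5; on the deposited scaling they run from −2.45 to −1.26 and from 3.26 to 1.14.

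Averaged over 2, 4 and 6 hpf, no gene passed for any morpholino of rs1a (limma, 17044 tested). In this model an effect that differs between times counts as residual spread, so an effect at 6 hpf alone is hard to call. The TUT47MO cleared median was 0.04 at 2 and 4 hpf and 1.25 at 6 hpf, so 0 calls are no sign of a lack of effect. For TUT4MO the smallest unadjusted p belonged to vamp5 (0.55 ± 0.16), fam212b (−0.69 ± 0.21), zp3a.1 (0.31 ± 0.10), tmem231 (−0.62 ± 0.20) and lfng (−0.50 ± 0.16). For TUT7MO they were asf1ba (0.41 ± 0.11), hbegfb (0.61 ± 0.17), cobll1a (0.73 ± 0.20), g3bp2 (−0.36 ± 0.11) and tmx1 (0.58 ± 0.17). For TUT47MO they were cobll1a (1.16 ± 0.20), CYSTM1 (1.05 ± 0.21, 2 entries share its symbol), myo10 (−0.78 ± 0.17), plekhj1 (0.66 ± 0.15) and hbegfb (0.74 ± 0.17). Against TUT4MO, TUT47MO gave epcam (0.49 ± 0.11), arl13a (−1.72 ± 0.40), slc29a2 (0.91 ± 0.21), gne (−0.53 ± 0.13) and fam134c (−0.63 ± 0.16). Against TUT7MO it gave nap1l4a (−0.57 ± 0.16), sqstm1 (−0.47 ± 0.14), ap3s2 (0.56 ± 0.18), colec12 (−0.61 ± 0.21) and smox (−0.43 ± 0.15). Limma called 0 genes for TUT4MO, TUT7MO, TUT47MO, TUT47MO against TUT4MO and TUT47MO against TUT7MO, with 205, 692, 1939, 781 and 179 at an unadjusted p under 0.05. Without the 6 hpf libraries limma called 2, 10 and 6 genes for TUT7MO, TUT47MO and TUT47MO against TUT4MO. DESeq2 called 1, 2, 29, 6 and 0, and edgeR 0 in each, with 291, 933, 2068, 916 and 214 at an unadjusted p under 0.05.

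The gene lists at 6 hpf were compared by their medians alone, a choice made after seeing the data. Against ConMO, 36 maternal-effect and oocyte genes had a median log2 ratio of 0.62 in TUT4MO, 1.49 in TUT7MO and 1.55 in TUT47MO. The medians of 43 mesendoderm genes were −0.32, −1.34 and −1.76, and those of 86 ribosomal protein genes −0.33, −1.15 and −1.41. TUT4MO and TUT7MO values come from 1 rs1a library each and TUT47MO values from the 6 hpf pairs of rs1a and rs1b, so these differences between morpholinos have no replicate check. In rs1a the morpholinos share 1 control library, so part of their likeness may come from it.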

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

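The tests of scaling were chosen only after the result was seen, while the tests of developmental delay over all 3 late libraries and of other splits were chosen before.

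The late and early effects of the TUT4 and TUT7 morpholinos differed, by the limma test of the difference itself, for 4478 genes with a higher and 4466 with a lower late effect, 2809 and 2519 with the deposited scaling, 1976 and 2573 without the pair block, 1501 and 1495 without rs1a and 2044 and 1814 without rs1b. The named genes with the largest differences were her5 (2.94), fam65c (2.81), pik3ap1 (2.80), lipin2 (2.77) and lipg (2.77) on the higher side and lcp1 (−6.12), abcc6b.2 (−4.96), TSTA3 (−4.88), alcamb (−4.80) and hkdc1 (−4.76) on the lower side, whose differences mostly restate the late change (at most 1.03 CPM in early ConMO). Of the 10 splits of the 6 late libraries, 1 (the real one) gave as many genes, with 8944 for the difference and 11624 for the late effect against at most 0 in the others, and 10 splits are too few for a share under 0.05. Only 4 of the 10, the real one included, part all 3 matched pairs, and the other 6 part 1 pair and estimate the effect from it alone. In every split but the real one, the real late effect enters the residual spread. Low counts there follow from the design and do not show what chance would give. The control comparison gave 12483 genes in 1 of its 10 splits and at most 0 in the others, again too few splits and with the same limit on the others. For the early effect and the 5 rs1a contrasts all 10 splits gave 0 genes, the real one included.

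The late shift of the cleared and zygotic classes may reflect a slower course of development, a change in how maternal mRNA is removed, or both. The tables argue against scaling as the whole cause, since with the values as deposited the zygotic medians of the late pairs were at most −1.06 and the cleared medians at least 1.25, with the cleared class 1.06 to 1.14 above the stable one. A delay alone would keep TUT47MO levels inside the range that control embryos pass through, and 3 of 18071 genes (the clone-named zgc:64022, proca1 and ddx51) lay over 1 log2 unit outside the range of the 7 control libraries in all 3 late TUT47MO libraries, as against 0 early, so this test did not argue against delay. A test chosen after the result was seen took the 6 hpf libraries alone. There 55 genes lay as far outside in both TUT47MO libraries, 43 above and 12 below, against at most 0 for any 2 early ones. The early pairs showed no shift, so their 0 does not measure how many genes late spread alone would place outside. For the 55 genes the 6 hpf levels argue against a delay as the whole cause, at the hours sampled. Of the late calls 65.1% had all 3 late levels inside that range, which a delay and a block of mRNA decay both allow. The biological effects of the morpholinos on clearance and on developmental pace cannot be told apart for genes inside the range, because embryo stage is not in the labels beyond the hour.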

How the results depend on the processing

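The deposited scaling, edgeR, pseudocounts for gene counts and the fit of 6 hpf alone were chosen after seeing the data. Of 191 alternative values for gene counts and class differences, 164 kept their direction and stayed within 1.5 times of the reported count or on the same side of the threshold, 13 were lower or lost, 14 were higher and 0 turned direction. Many of the 164 say little. A reported count of 0, as for the early and rs1a comparisons, could not become lower. Class differences could change only by turning sign, since 3 pairs cannot give a sign-flip p under 0.25. Of 1514 alternative values for named genes with a call 1469 kept it, 45 lost it and 0 turned; of 461 for named genes without a call 26 gained one. In 15 late alternatives 0 shared calls turned direction. The planned ERCC scaling was not run.

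With the deposited scaling the late median of all genes moved by 0.27, the early one by 0.19, the difference by 0.12 and the control one by −0.26. It gave 3161 late lower, 2809 and 2519 for the difference, 2592 and 2045 in controls and 3 early higher. Read depth in rs1b, which the deposited scaling leaves uncorrected, enters these values. Without the replicate block there were 3780 late higher genes and 1976 and 2573 for the difference; lost calls of named genes under it were those of trim25 (0.70), papd7 (0.86), ZCCHC6 (−0.46) and 4 mitochondrial genes (−0.64 to −0.71), with folds as before and differences between sets added to the spread, and no count of early or control genes changed its call. Leaving out 1 set gave 3904 to 6880 late higher, 4011 to 6258 late lower, 1501 to 5740 for a higher and 1495 to 5525 for a lower late effect; the lowest came without rs1a, except late lower. Fewer libraries entered these fits. The 6 libraries of a phase alone gave 1 early gene (5.8S rRNA) and 4670 and 4338 late. With the 4 hpf pair counted as late the calls of krt4 (−1.66), ta (−1.66), trim25 (0.49), mt-nd4l (−0.42), ZCCHC6 (−0.32), PAPD5 (0.59) and papd4 (−0.39) were lost.

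DESeq2 gave 1, 2, 29 and 6 genes for TUT4MO, TUT7MO, TUT47MO and TUT47MO against TUT4MO. Leaving out 1 time gave 0 to 2, 0 to 10 and 0 to 6 for TUT7MO, TUT47MO and TUT47MO against TUT4MO, the highest without 6 hpf. The 6 hpf fit gave 6686, 12022, 14502, 9356 and 1476, but it rests on lone libraries and on a spread taken largely from early pairs, so these counts support no statement here. The cause was not tested for any of these. The cleared minus stable difference ran from 0.849 to 1.58 and the zygotic one from −1.23 to −2.42 over all class alternatives. Camera with its preset correlation called 31 of 72 list tests of the early, late, difference and control comparisons, and with an estimated correlation all 31 were lost. List tests of the rs1a comparisons are not counted here. Fry lost 5 of the 31, and of the other 41 it gained 10 and turned 1: reported miR-430 targets turned upwards at 0.0291. Depth limits genes near 1 CPM.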

Other observations

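The tests of genes outside the control range at 6 hpf, of p53 targets among them and of the 4 hpf libraries were chosen only after the result was seen; those of clearance time and of clearance strength were chosen before.

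Genes above any control level at 6 hpf included cell cycle arrest and apoptosis genes, chosen here after their values were seen. The kinase inhibitor gene cdkn1a stood at 5.84 CPM in ConMO, 5.65 in TUT4MO, 56.0 in TUT7MO and 40 in TUT47MO at 6 hpf of rs1a, at 5.24 and 53.8 CPM in ConMO and TUT47MO of rs1b, and at 3.86 and 2.94 CPM at 5 hpf of rs2. The apoptosis gene bbc3 was at 7.85, 11.7, 43.7 and 45.3 CPM in the same 4 rs1a libraries, 7.48 and 41.9 CPM in rs1b and 4.09 and 4.92 CPM in rs2. In those rs1a libraries sesn1 was at 17.0, 38.1, 91.9 and 81.4 CPM and gadd45aa at 4.47, 7.09, 24.2 and 19.97 CPM, so levels in TUT4MO lay above ConMO for 3 of the 4 genes. Late limma adjusted p was 0.0254 for cdkn1a, 0.00809 for bbc3, 0.00759 for gadd45aa and 0.000283 for sesn1, whereas mdm2 gave −0.16 ± 0.14 (adjusted p = 0.326).

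At 6 hpf 55 genes lay over 1 log2 unit outside the range of the 7 control libraries in both TUT47MO libraries, 43 above and 12 below, against at most 0 for any 2 early TUT47MO libraries. The early pairs showed no shift, so their 0 does not measure how many genes late spread alone would place outside. The test planned over all 3 late libraries gave 3 genes and did not argue against delay. For the 55 of 18071 genes at 6 hpf, the levels argue against a delay as the whole cause. Control embryos held no such level at the hours sampled, and a peak or dip between those hours was not tested. A p53 response may account for a part: 4 members of the p53 target list (cdkn1a, bbc3, gadd45aa and sesn1) were among the 43 (Fisher's exact test p = 1.61e-07, adjusted p = 3.07e-06 over 19 lists). Because the test was chosen after these members had been seen, its p describes the overlap and is no independent support. Of 2 more lists with an adjusted p under 0.05, interferon-induced genes gave 2 members (0.00971) and early zygotic regulators 2 (0.021). Injection as such was shared by ConMO embryos, but whether the response comes from the loss of TUT4 and TUT7 or from another effect of their oligomers was not tested, since no rescue library is used here.

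In rs1a at 4 hpf the TUT7MO and TUT47MO libraries held 44.7 and 44.6% mitochondrial rRNA, against 14.4% in ConMO. A difference in library preparation could account for this: 99 small structured RNAs were higher than in ConMO by medians of 0.76 in TUT7MO, 0.64 in TUT47MO and 0.02 in TUT4MO at 4 hpf, but by 0.74, 0.70 and 0.42 in TUT4MO, TUT7MO and TUT47MO at 2 hpf, where mitochondrial rRNA did not stand apart. For an effect of the knockdown already at 4 hpf, the cleared minus stable difference was 0.0878 in TUT47MO, 0.0805 in TUT7MO and 0.0575 in TUT4MO. All lay under 0.1, the bound set for no such effect, but that bound cannot show a lack of effect. From 2 to 4 hpf the ConMO medians of rs1a changed by only −0.12 (cleared) and 0.08 (stable), so there was little clearance to block. An effect also stays open because 0.0878 lies under the bound by less than the SD of the 3 early TUT47MO pairs (0.0173). That condition was itself added after the value was seen. The labels give no preparation batch, so the 2 explanations cannot be told apart.

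A hypothesis was that genes cleared after 4 hpf respond more than genes cleared before. The medians differed by 0.60 in rs1b at 6 hpf (95% bootstrap interval 0.404 to 0.867) and by 0.127 in rs2 at 5 hpf (−0.00943 to 0.303), over 3047 and 114 genes. The intervals come from resampling genes within 1 pair and hold no spread between embryos or sets. The sets did not give 1 answer, and set and hour differ together, so the reason cannot be told. A second hypothesis was that stronger clearance in control embryos goes with a larger late response. Across cleared genes the slope of the response on the control change of the other sets was −0.604 in rs1a, −0.648 in rs1b and −0.442 in rs2, and genes are not independent replicates. Such slopes would follow from less clearance of each mRNA in proportion to its normal loss, which a delay would also give. The groups of the first hypothesis went against that proportion. Genes cleared before 4 hpf fell more in ConMO of rs1a than those cleared after (medians −2.41 and −1.69). Their response was nevertheless lower, at 0.78 against 1.38 in rs1b and 0.83 against 0.95 in rs2.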
